A study of Mus musculus with 6 samples.

How the data were processed

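The data are RNA sequencing counts from 6 libraries, 3 of WT and 3 of NFS1 KO effector CD8+ T cells of the mouse, whose RNA was isolated with a Qiagen RNeasy kit, per the labels. The authors deposited 1 table of whole-number counts per gene, with 54532 versioned Ensembl gene identifiers and 6 columns. The submitters' processing notes name STAR, featureCounts, DESeq2 and deepTools and the mouse build mm10; their versions, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Counts of genes with near-identical copies, of overlapping genes and of antisense genes are therefore uncertain. The values were used as deposited, without any normalization by the authors. Samples were grouped by the genotype in the labels. The knockout columns of the table are spelled NFS1 and those samples' titles NSF1; they were matched by that name and number, and every column was mapped.

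Gene symbols, coordinates and transcript lengths came from the GENCODE mouse release 21 annotation of the same build, matched on the identifier without its version: 54495 of 54532 rows matched, and the other 37 held 0.0051% of the counts and kept their identifier. Total counts ran from 14094369 to 20985135 per library, so 1 count equalled 0.048 to 0.071 CPM; this covers counting error only. No library was a copy of another: the chi-square statistic per degree of freedom over genes with at least 10 counts ran from 6.44 to 103 between pairs of libraries, and the closest pair, WT replicate 3 and NFS1 KO replicate 2, crossed the genotypes.

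The main test was edgeR 4.0.16's quasi-likelihood test (R 4.3.3) with genotype as the only term, TMM normalization, filterByExpr (14796 genes kept), robust dispersion estimates and Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 27.0%. Standard errors were the absolute log2 fold change over the square root of the F statistic. CPM values were computed with the TMM factors, and log2 fold changes are NFS1 KO over WT. A set of 27 gene lists, on iron-sulfur biology, mitochondria, stress, the cell cycle, T cell states and metabolism, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Where the text gives an adjusted p for a list, it is camera's. The 9 lists of cell type markers were used as levels only.

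The design, the lists and the rule for the genes named were set before the data were examined. The rule took Nfs1; the 12 genes with the largest positive and the 12 with the largest negative fold changes among named genes past the threshold with a mean of at least 10 CPM in a genotype and no overlap between genotypes, of which there were 0; up to 4 genes per list with the smallest p; and up to 3 genes per marker list with the highest CPM. Genes outside it are said to have been chosen after their values were seen. Lists of 8 markers each for 11 organs, liver among them, were written after the libraries had been examined but before those genes were looked at.

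Alternatives were DESeq2 1.42.0's Wald test, limma voom, DESeq2 size factors, total counts, upper-quartile factors, no filter and a stricter filter (a mean of 5 CPM in a genotype), dispersions that were not robust, the replicate number as a block, each library left out in turn and an adjusted p under 0.01. For the lists they were an estimated correlation, the self-contained test fry and a prior count of 0.5. DESeq2 size factors, total counts and the same filters, block and left-out libraries were used as well, but not the upper-quartile factors. Added after the data were seen were voom with library quality weights, DESeq2 as a second result under its own alternatives, removal of a trend on transcript length and GC content from the lists, the log2 liver transcript level as a covariate, and the omission of 864 genes that kept a near-constant ratio to the liver transcripts (a coefficient of variation under 0.2 over the 6 libraries, at a mean over 2 CPM).

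The steps were tested on simulated counts for NFS1 KO against WT, drawn with these libraries' means, sizes and gene-wise dispersions over 14476 genes. At an adjusted p under 0.05 edgeR recovered 21% of genes changed 2-fold and 83% of those changed 4-fold, and called 0.0702% of unchanged genes; DESeq2 recovered 48% and 94% and called 0.246%. Camera recovered a shift of 0.5 (log2) put into the p53 list and called 1 of 26 other lists. The simulated genes varied independently, whereas the estimated correlation in the real mitosis list was 0.47. The simulation therefore cannot show how often camera, at the preset 0.01, calls lists of correlated genes in error.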

Results

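RNA sequencing compared effector CD8+ T cells, the lymphocytes that kill infected and malignant cells, from 2 genotypes. Per the labels the cells came from spleen and lymph nodes and RNA was taken from 3 wild-type (WT) and 3 NFS1 knockout (NFS1 KO) samples. NFS1 is the cysteine desulfurase that takes sulfur from cysteine for iron-sulfur clusters, and the series title sets the comparison in the question of how sulfur from cysteine serves T cell proliferation and effector function. Total counts over genes were 16598291, 20232836 and 17559387 in WT replicates 1 to 3, and 20985135, 17050007 and 14094369 in NFS1 KO replicates 1 to 3. The labels do not say whether the 3 samples of a genotype came from separate mice or cultures, so p-values measure the spread between these samples, which may be technical.

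The libraries carried high levels of CD8 T cell transcripts in both genotypes. A set of 12 identity genes, among them Cd8a, Cd3e and Lck, summed to 4774, 5540 and 6119 CPM (counts scaled to a common library size) in WT and to 6660, 5914 and 5963 CPM in NFS1 KO. Liver transcripts were abundant as well. Alb, which encodes serum albumin, and 7 other hepatocyte genes summed to 10460, 6329 and 9012 CPM in WT replicates 1 to 3, and to 2158, 9703 and 8703 CPM in NFS1 KO replicates 1 to 3. Collagen and matrix genes (Col1a1, Col1a2, Col3a1, Dcn and Sparc) summed to 133, 82.8 and 120 CPM in WT and to 27.3, 126 and 108 CPM in NFS1 KO. Macrophage, monocyte and neutrophil markers summed to 111, 69.9 and 99.1 CPM in WT and to 30.4, 108 and 92.0 CPM in NFS1 KO. In each of these 3 sets NFS1 KO replicate 1 was the lowest library, and it also stood apart from the other 5 on the first principal component, which held 54.5% of the variance. B cell markers did not follow that order. They summed to 149, 309 and 647 CPM in WT and to 181, 555 and 246 CPM in NFS1 KO, nearly all from the immunoglobulin heavy chain gene Ighm. Mitochondrially encoded transcripts took 1.26% to 2.52% of the counts.

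**Figure D1:**
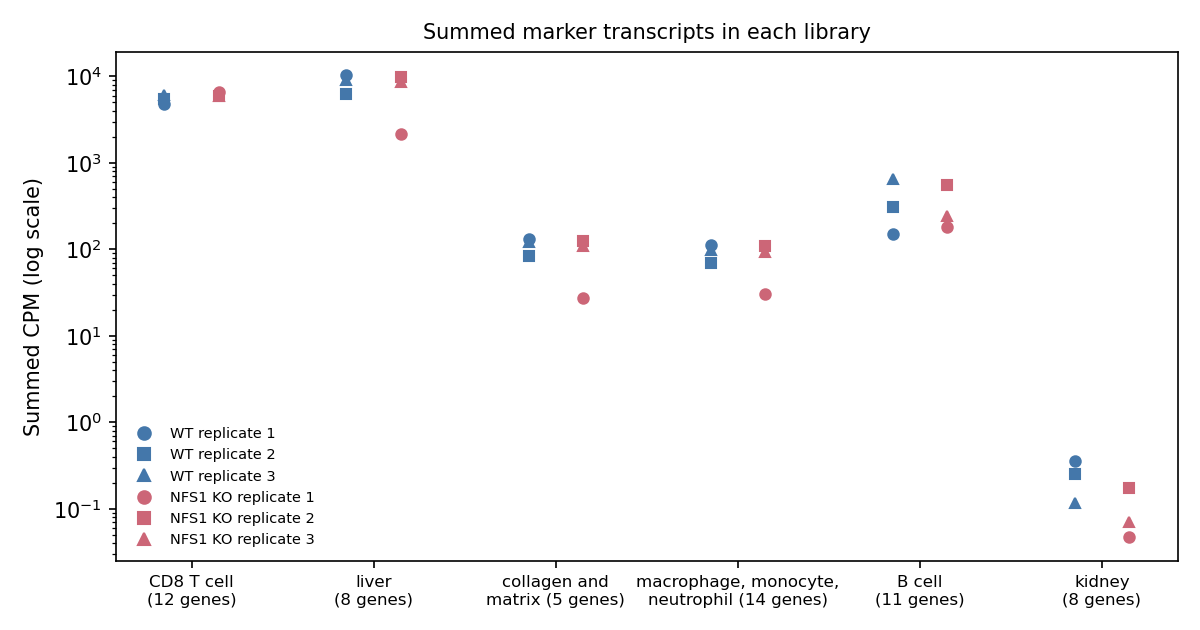
Summed CPM of marker genes (vertical axis, log scale) for 6 sets of genes, with 1 point for each library (blue WT, red NFS1 KO; the symbol gives the replicate number). The CD8 T cell genes were at similar sums in all libraries, while the liver genes reached 6329 to 10460 CPM in 5 libraries and 2158 CPM in NFS1 KO replicate 1; the kidney genes summed to at most 0.356 CPM.

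Nfs1 transcript was lower in the NFS1 KO libraries. The gene (ENSMUSG00000027618.17; mouse build mm10, chromosome 2, 156123639 to 156144186, minus strand, protein coding) had 37.9, 34.8 and 35.0 CPM in WT replicates 1 to 3, from 638, 690 and 600 counts. It had 23.9, 31.4 and 24.7 CPM in NFS1 KO replicates 1 to 3, from 512, 533 and 349 counts. The means were 35.9 ± 1.75 CPM in WT and 26.7 ± 4.09 CPM in NFS1 KO (SD, n = 3 each), a level 25.7% lower. All 3 NFS1 KO values lay below all 3 WT values, and they were 33.3%, 12.6% and 31.3% below the WT mean. The log2 fold change was -0.43 (SE 0.16), and a two-sided exact permutation test on the CPM gave p = 0.1, the smallest p that 3 against 3 samples allow. Over all genes the edgeR adjusted p was 0.971. Each count covers the whole gene, and how the knockout was made is not given in the sources used here. A frameshift need not remove the transcript, so the level does not measure the loss of the protein. Its direction goes with the labels but is a weak check of them. In 718 of 14796 genes all 3 NFS1 KO values lay below all 3 WT values, near the 5% that chance gives.

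Between NFS1 KO and WT, genes controlled by the tumour suppressor p53 were higher, and genes of mitosis, glycolysis, the hypoxia response, cholesterol synthesis and fatty acid synthesis were lower. These changes were seen over gene lists, while single genes passed an adjustment over all genes only in some fits. edgeR's quasi-likelihood test over 14796 genes called 0 genes at an adjusted p under 0.05, with 620 genes at an unadjusted p under 0.05. DESeq2 called 46 genes, 39 higher and 7 lower in NFS1 KO, and limma voom called 0. DESeq2's count rested on single libraries: it was 406 without NFS1 KO replicate 2 and 13 without WT replicate 2, and edgeR called 36 genes without NFS1 KO replicate 2. Of the 27 gene lists fixed before the data were examined, camera called 12, 5 higher and 7 lower, at an inter-gene correlation preset at 0.01. With a correlation estimated for each list it called 0, and the self-contained test fry called 0, so each list's p with an estimated correlation stands beside its call. That setting raised p even where the estimate lay below the preset. For the inhibitory receptor list, with an estimate of -0.023, camera's unadjusted p went from 0.0015 to 0.026. The p-values with an estimated correlation therefore reflect more than the correlation.

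**Figure D2:**
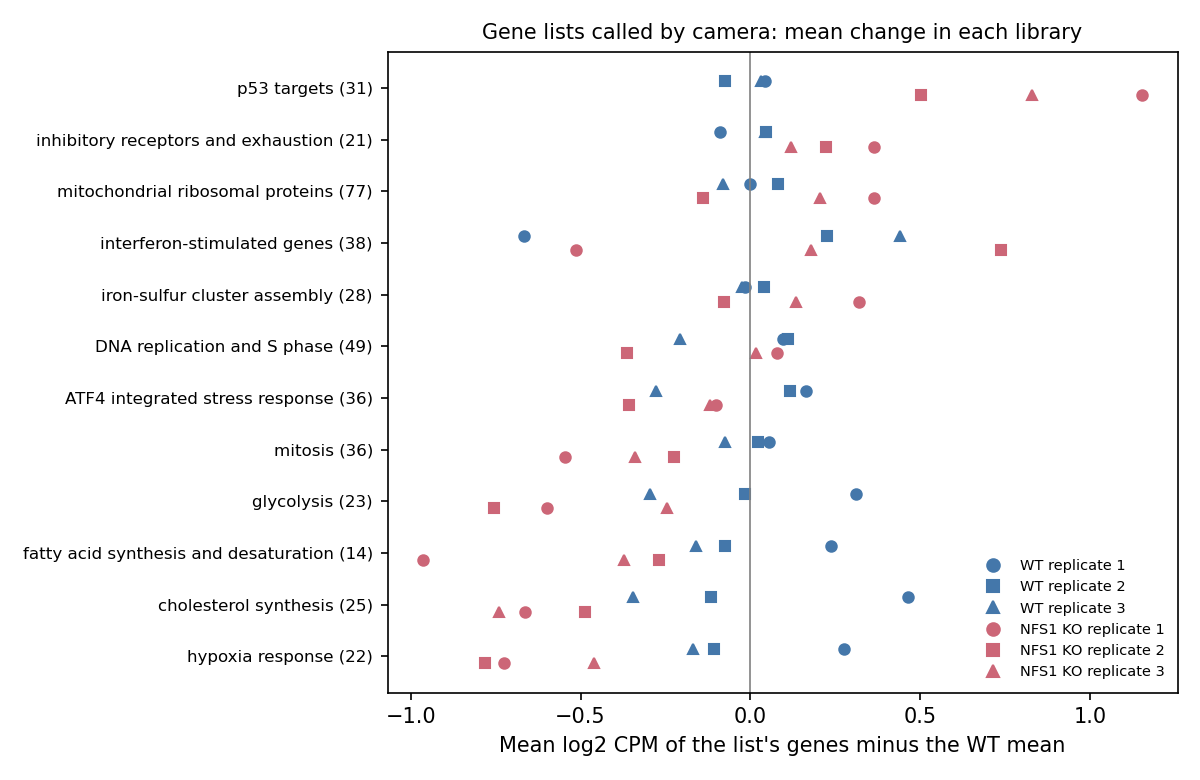
Mean log2 CPM of the genes in each called list, relative to the mean of the 3 WT libraries (horizontal axis), with 1 point for each library (blue WT, red NFS1 KO) and the number of tested genes in brackets. For the p53 targets the NFS1 KO libraries sit at 0.50 to 1.15 and the WT libraries at -0.08 to 0.04, whereas for the interferon-stimulated genes the libraries of both genotypes overlap.

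Targets of p53, which halts the cell cycle and starts cell death after damage, rose in NFS1 KO. The 31 tested targets had a mean log2 change of 0.83, a 1.77-fold higher level (camera adjusted p = 3.1e-15, and adjusted p = 0.23 with an estimated correlation). Of the 31 targets 27 had a positive fold change, and in 18 all 3 NFS1 KO values lay above all 3 WT values. With p-values adjusted over the list alone, edgeR called 17 targets, all higher; adjusted over all genes it called 0, and DESeq2 called 6. Plk2, a kinase of the cell cycle, had 5.17, 6.35 and 5.42 CPM in WT and 45.3, 10.7 and 28.7 CPM in NFS1 KO (log2 fold change 2.32, SE 0.48). Zmat3, an RNA-binding p53 target, was at 53.1 ± 4.75 CPM in WT and 182 ± 69.5 CPM in NFS1 KO (SD, n = 3; log2 fold change 1.78, SE 0.29), and Sesn2, a stress-induced inhibitor of mTORC1 signalling, at 29.9 ± 2.60 and 82.5 ± 33.7 CPM (log2 fold change 1.46, SE 0.30). Dcxr, a carbonyl reductase, had a log2 fold change of 1.66 (SE 0.34). The cell cycle inhibitor Cdkn1a (log2 fold change 2.07), the p53 ubiquitin ligase Mdm2 (0.93) and the cell death gene Bax (1.25), named after their values were seen, were among the 17. Cdkn1a had 117, 89.2 and 56.2 CPM in WT replicates 1 to 3 and 649, 123 and 331 CPM in NFS1 KO replicates 1 to 3. The size differed between the knockout libraries: the list mean was 1.15 in NFS1 KO replicate 1, 0.50 in replicate 2 and 0.83 in replicate 3.

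Glycolysis genes fell in NFS1 KO. The 23 tested genes had a mean log2 change of -0.53, a 1.45-fold lower level (camera adjusted p = 9.8e-11, and adjusted p = 0.41 with an estimated correlation), and 21 of them had a negative fold change. Adjusted over the list alone, edgeR called 9, 8 lower and 1 higher; DESeq2 called 3 lower and 1 higher. The aldolase gene Aldoc had 47.3, 33.9 and 37.2 CPM in WT and 13.9, 23.1 and 14.8 CPM in NFS1 KO (log2 fold change -1.19, SE 0.24). Its paralog Aldoa (ENSMUSG00000030695.16) was at 1713 ± 336 CPM in WT and 932 ± 173 CPM in NFS1 KO (SD, n = 3; log2 fold change -0.88, SE 0.20), and the glucose transporter gene Slc2a3 at 185 ± 5.41 and 108 ± 22.8 CPM (log2 fold change -0.78, SE 0.17). Ldhb, which encodes the lactate dehydrogenase subunit that favours lactate use, was higher, at 3.63 ± 0.438 and 9.01 ± 2.57 CPM (log2 fold change 1.31, SE 0.30). The lactate exporter gene Slc16a3, named after its values were seen, was 3.09-fold lower (DESeq2 adjusted p = 0.043, edgeR adjusted p = 0.971). The WT libraries were themselves spread, at 0.31, -0.01 and -0.30 around their mean, and NFS1 KO replicate 3 at -0.24 lay above WT replicate 3. Several glycolysis genes have processed pseudogene copies with which reads can be shared.

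The hypoxia response list, genes switched on by hypoxia-inducible factors, also fell. Its 22 tested genes had a mean log2 change of -0.66, a 1.58-fold lower level (camera adjusted p = 9.8e-11, and adjusted p = 0.23 with an estimated correlation); 21 had a negative fold change, and edgeR called 7 adjusted over the list alone, all lower. All 3 NFS1 KO libraries (-0.73, -0.78 and -0.46) lay below all 3 WT libraries (0.28, -0.11 and -0.17). Egln1, an oxygen-sensing prolyl hydroxylase, had a log2 fold change of -0.63 (SE 0.18), Ndrg1 of -0.64 (SE 0.18), the oxidative folding gene Ero1l of -0.74 (SE 0.21) and P4ha2, a subunit of collagen prolyl hydroxylase, of -1.49 (SE 0.43). Rora, a member with a negative fold change, followed the liver transcripts from library to library.

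Cholesterol synthesis genes fell as a list. The 25 tested genes had a mean log2 change of -0.63, a 1.55-fold lower level (camera adjusted p = 2.0e-14, and adjusted p = 0.41 with an estimated correlation). All 25 had a negative fold change, and edgeR called 14 adjusted over the list alone. Nsdhl, a sterol dehydrogenase, had 48.2, 40.8 and 36.1 CPM in WT and 26.1, 30.3 and 24.0 CPM in NFS1 KO (log2 fold change -0.64, SE 0.17). The log2 fold change was -0.72 (SE 0.20) for the sterol carrier gene Stard4, -0.85 (SE 0.27) for Insig1, a brake on sterol synthesis, and -0.98 (SE 0.31) for Fdps, an enzyme of the mevalonate pathway. All 3 NFS1 KO libraries lay below all 3 WT libraries, which were spread from -0.35 to 0.46. Without WT replicate 1, the highest of them, the list mean was -0.38, with the call kept.

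The 14 tested genes of fatty acid synthesis and desaturation fell as a list, by 0.54 on the log2 scale (camera adjusted p = 6.3e-07, and adjusted p = 0.42 with an estimated correlation). Of the 14 genes 13 had a negative fold change, and edgeR called 0 adjusted over the list alone. Scd2, a fatty acid desaturase, had 1405, 1129 and 1037 CPM in WT and 356, 826 and 532 CPM in NFS1 KO (log2 fold change -1.06, SE 0.30). Acsl3 had a log2 fold change of -0.85 (SE 0.23) and Acly, which makes cytosolic acetyl-CoA, of -0.43 (SE 0.14). NFS1 KO replicate 1, the library with the least liver transcript, was lowest at -0.96, and replicates 2 and 3 were at -0.27 and -0.37. Without replicate 1 the list mean was -0.32 (adjusted p = 6.3e-06). The desaturase gene Scd1 followed the liver transcripts over the 6 libraries.

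Mitosis genes were lower as a list. All 36 had a negative fold change, and in 30 all 3 NFS1 KO values lay below all 3 WT values. The mean log2 change was -0.37, a 1.29-fold lower level (camera adjusted p = 2.2e-17, and adjusted p = 0.41 with an estimated correlation), and edgeR called 0 adjusted over the list alone, with 21 at an unadjusted p under 0.05. The mitotic kinesin gene Kif20a had 273, 274 and 247 CPM in WT and 166, 206 and 190 CPM in NFS1 KO (log2 fold change -0.50, SE 0.13). Ccnb1, which encodes cyclin B1, had a log2 fold change of -0.51 (SE 0.15), and the spindle checkpoint gene Bub1b of -0.48 (SE 0.14). The DNA replication and S phase list moved little: its mean over 49 genes was -0.09 (adjusted p = 0.032, and adjusted p = 0.87 with an estimated correlation). That call was lost without WT replicate 1 (adjusted p = 0.59), WT replicate 2 (adjusted p = 0.59) or NFS1 KO replicate 2, where the mean turned to 0.05 (adjusted p = 0.35), and the mean was -0.19 without WT replicate 3 and -0.18 without NFS1 KO replicate 1. It was also lost with DESeq2 size factors (adjusted p = 0.0507), total counts alone (adjusted p = 0.0508), no filter (adjusted p = 0.22), the replicate number as a block (adjusted p = 0.083) and the length and GC correction, which was added after the data were seen (adjusted p = 0.15). Mcm7, a subunit of the replicative helicase, had a log2 fold change of -0.38 (SE 0.14).

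**Figure D3:**
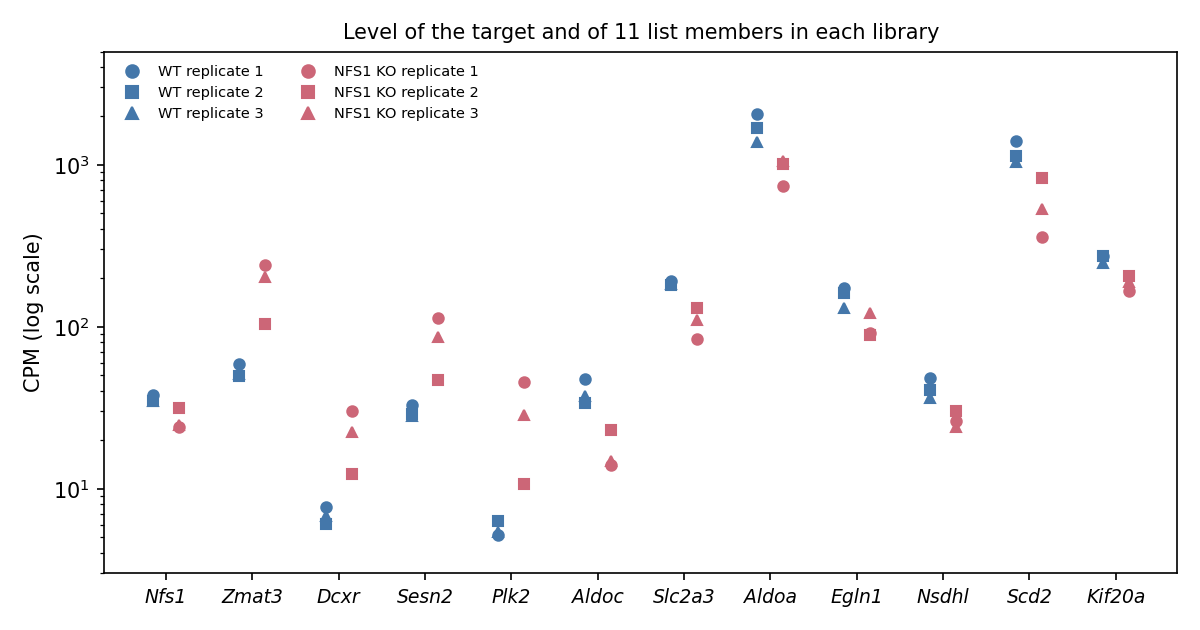
CPM (vertical axis, log scale) of Nfs1 and 11 members of the changed lists, with 1 point for each library (blue WT, red NFS1 KO; the symbol gives the replicate number). Zmat3, Dcxr, Sesn2 and Plk2 are higher in all 3 NFS1 KO libraries, with replicate 2 nearest to WT (10.7 CPM for Plk2), and Nfs1 and the other 7 are lower in all 3.

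Genes of the pathway that NFS1 itself feeds changed little. The iron-sulfur cluster assembly list, which left out Nfs1, had a mean log2 change of 0.13 over 28 genes, 24 of them positive (camera adjusted p = 0.032, and adjusted p = 0.84 with an estimated correlation). The call was lost without NFS1 KO replicate 1, where the mean was 0.03 (adjusted p = 0.87), and without WT replicate 1 (adjusted p = 0.10), WT replicate 3 (adjusted p = 0.088) or NFS1 KO replicate 3 (adjusted p = 0.086), where the means were close to that of all libraries, at 0.13, 0.11 and 0.13. It was also lost with the liver transcript level as a covariate (adjusted p = 0.49) and without the genes that followed the liver transcripts (adjusted p = 0.061), both alternatives added after the data were seen, and the mean was 0.23 without NFS1 KO replicate 2. Isca2, a late assembly factor, had a log2 fold change of 0.46 (SE 0.19) and Gfer, a sulfhydryl oxidase, of 0.62 (SE 0.25). The 77 mitochondrial ribosomal protein genes had a mean of 0.14, 68 of them positive (adjusted p = 5.5e-05, and adjusted p = 0.84 with an estimated correlation). Their call was lost without NFS1 KO replicate 1, where the mean was 0.03 (adjusted p = 0.72), and with the liver covariate (adjusted p = 0.24), and their mean was 0.29 without NFS1 KO replicate 2. Mrpl33 had a log2 fold change of 0.63 (SE 0.27) and Mrps18a of 0.45 (SE 0.19).

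Lists for proteins that hold iron-sulfur clusters, or depend on them, passed no threshold at camera's main setting with all 6 libraries. For 32 iron-sulfur proteins outside the respiratory chain camera's direction was up, against the sign of the list's mean and median. The mean log2 change was -0.02 for these proteins (adjusted p = 0.83). It was 0.05 for respiratory complex I (adjusted p = 0.23), 0.04 for complexes II to V (adjusted p = 0.47) and 0.23 for the mitochondrially encoded genes (adjusted p = 0.11). Without NFS1 KO replicate 2, complex I (0.12, adjusted p = 0.018) and complexes II to V (0.12, adjusted p = 0.019) passed the threshold, and without NFS1 KO replicate 1 both means were near 0, at 0.0044 and -0.0038. The mitochondrially encoded genes passed it without WT replicate 3 (0.48, adjusted p = 0.00014) or NFS1 KO replicate 1 (0.34, adjusted p = 0.039) and with the liver covariate (0.35, adjusted p = 0.025), whereas their mean was 0.04 without WT replicate 2 and 0.07 without NFS1 KO replicate 2. The tricarboxylic acid cycle stood at -0.05 (adjusted p = 0.27), the lipoic acid pathway at -0.03 (adjusted p = 0.82), heme synthesis and export at -0.12 (adjusted p = 0.24) and iron uptake, storage and sensing at -0.06 (adjusted p = 0.58). Without WT replicate 1 these 4 means were -0.01, 0.02, -0.02 and 0.04, and without WT replicate 3 they were -0.09, -0.08, -0.15 and -0.11. The tricarboxylic acid cycle mean was 0.01 without NFS1 KO replicate 2. In the mitochondrially encoded genes the spread ran across both genotypes: WT replicate 3 and NFS1 KO replicate 2 were at 0.51 and 0.55 and WT replicate 2 at -0.36.

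Stress and amino acid lists gave 1 call at camera's main setting with all 6 libraries. The ATF4 integrated stress response list, genes induced by amino acid or mitochondrial stress, was lower by a mean of 0.19 on the log2 scale over 36 genes, 25 of them with a negative fold change (adjusted p = 0.0039, and adjusted p = 0.84 with an estimated correlation). The call was lost without WT replicate 1 (mean -0.10, adjusted p = 0.10), WT replicate 2 (mean -0.13, adjusted p = 0.14) or NFS1 KO replicate 2 (mean -0.11, adjusted p = 0.42), and the mean was -0.33 without WT replicate 3. Its members did not move together: Sesn2, also a p53 target, had a positive fold change, while the asparagine synthetase gene Asns was at -0.72 (SE 0.22) and the proline synthesis gene Pycr1 at -0.90 (SE 0.33). NRF2 antioxidant targets had a mean of -0.14 (adjusted p = 0.11; -0.19 and adjusted p = 0.014 without WT replicate 3, -0.15 and adjusted p = 0.040 with the stricter filter) and glutathione and cysteine metabolism also -0.14 (adjusted p = 0.14). The NRF2 mean was -0.03 without WT replicate 1 and -0.06 without NFS1 KO replicate 1, and the glutathione mean was 0.01 without NFS1 KO replicate 1. In the glutathione and cysteine list 5 of 32 genes (Cth, Cbs, Tst, Cdo1 and Bhmt2) followed the liver transcripts from library to library, and NFS1 KO replicate 1 was at -0.44 against 0.00 and 0.03 in replicates 2 and 3. Mitochondrial chaperones and proteases had a mean of 0.04 (adjusted p = 0.67), one-carbon metabolism and purine synthesis of -0.02 (adjusted p = 0.68) and cytosolic ribosomal proteins of 0.00 (adjusted p = 0.82; mean and median of opposite sign). The chaperones passed the threshold without NFS1 KO replicate 2 (0.22, adjusted p = 0.012) and had a mean of -0.07 without NFS1 KO replicate 1. The one-carbon list passed it without WT replicate 3 (-0.15, adjusted p = 0.045) and had a mean of 0.16 without NFS1 KO replicate 2. Cytosolic ribosomal proteins passed it in opposite directions without WT replicate 1 (-0.081, adjusted p = 0.0053) and without WT replicate 3 (0.082, adjusted p = 0.024).

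Among T cell state lists, that of inhibitory receptors and exhaustion genes was slightly higher in NFS1 KO. Their mean log2 change was 0.24 over 21 genes, 16 of them positive (camera adjusted p = 0.0046, and adjusted p = 0.23 with an estimated correlation), and edgeR called 0 adjusted over the list alone. Rgs16, a regulator of G protein signalling, had a log2 fold change of 0.58 (SE 0.23), Nr4a3 of 0.73 (SE 0.35) and the inhibitory receptor gene Btla of 0.96 (SE 0.47). The inhibitory receptor genes Ctla4, Lag3 and Pdcd1, named after their values were seen, had negative fold changes (log2 -0.43, -0.33 and -0.09), none past the adjustment over the list alone. Interferon-stimulated genes had a mean of 0.13 over 38 genes (adjusted p = 0.040, and adjusted p = 0.87 with an estimated correlation). The call was lost without NFS1 KO replicate 3 (adjusted p = 0.086), and the mean turned to -0.18 without WT replicate 1 and to -0.17 without NFS1 KO replicate 2. It was 0.25, 0.36 and 0.46 without WT replicate 2, WT replicate 3 and NFS1 KO replicate 1. The call was also lost with total counts alone (adjusted p = 0.051) and without the genes that followed the liver transcripts, an alternative added after the data were seen (adjusted p = 0.068). Mx1, an antiviral GTPase gene of that list, had 21.2, 30.5 and 33.7 CPM in WT and 89.2, 60.9 and 48.3 CPM in NFS1 KO (log2 fold change 1.22, SE 0.27; edgeR adjusted p = 0.971, DESeq2 adjusted p = 0.031).

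Cytotoxic effector molecules and regulators passed no threshold (mean log2 change 0.22 over 34 genes, adjusted p = 0.098), although they did without WT replicate 1 (0.37, adjusted p = 0.021), WT replicate 2 (0.28, adjusted p = 0.028) or NFS1 KO replicate 2 (0.40, adjusted p = 0.012). The mean was 0.00 without NFS1 KO replicate 1 and 0.03 without WT replicate 3, so it rested on single libraries. The chemokine genes Ccl4 and Xcl1 had log2 fold changes of 2.04 (SE 0.58) and 1.12 (SE 0.38), from low levels of at most 1.82 and 11.4 CPM in WT, and Ctsw had 0.50 (SE 0.18). None of these 3 passed edgeR's adjustment over the list alone or over all genes. The granzyme B gene Gzmb and the perforin gene Prf1, named after their values were seen, had log2 fold changes of 0.62 and 0.77 with unadjusted edgeR p-values of 0.36 and 0.25. The naive and memory T cell list had a mean of -0.12 (adjusted p = 0.74), with WT replicates at -0.63, -0.01 and 0.64 and NFS1 KO replicates at -0.59, 0.52 and -0.27. It passed the threshold in opposite directions, lower without WT replicate 1 (-0.41, adjusted p = 0.0018) or NFS1 KO replicate 2 (-0.43, adjusted p = 0.037) and higher without WT replicate 3 (0.20, adjusted p = 0.045).

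Markers of other cell types were also measured. Markers of CD4 and regulatory T cells summed to 49.8, 50.4 and 52.0 CPM in WT and to 74.6, 51.6 and 61.5 CPM in NFS1 KO. Most of each sum came from Zbtb7b, while Cd4 itself was at 0.71 to 0.89 CPM in WT and 0.92 to 1.70 CPM in NFS1 KO. The regulatory T cell gene Foxp3 was at 1.11 to 1.71 CPM in WT and 2.47 to 4.12 CPM in NFS1 KO (edgeR adjusted p = 0.971). Natural killer cell markers summed to at most 11.9 CPM and dendritic cell markers to at most 35.8 CPM. Gamma delta T cell markers summed to 135, 106 and 67.0 CPM in WT and to 185, 71.5 and 144 CPM in NFS1 KO, mostly from Tcrg-C2, whose near-identical copies make its count uncertain. Red blood cell markers summed to at most 8.40 CPM. Cd8a itself was at 403, 521 and 603 CPM in WT and 945, 623 and 800 CPM in NFS1 KO (log2 fold change 0.63, SE 0.21, edgeR adjusted p = 0.971).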

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

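DESeq2's alternatives, the quality weights, the length and GC correction and both liver alternatives were chosen after the data were seen. edgeR's 0 genes became 14 without a filter on low counts (10 higher, 4 lower, 12 at least 2-fold), 46 with DESeq2 in its place (39, 7 and 40) and 36 without NFS1 KO replicate 2 (34, 2 and 35); without any other library it stayed 0, as it did under the other scalings, filters and tools, a threshold of 0.01 and both liver alternatives. The cause was not tested beyond the simulated counts. There DESeq2 recovered more of the changed genes, but it also called 0.246% of 14246 unchanged genes, against 0.0702% for edgeR. For DESeq2 that share is a number of false calls of the same order as its 46 calls in these data. An unknown part of the 46 may therefore be false calls. DESeq2's 46 genes ranged from 13 (12 higher, 1 lower; without WT replicate 2) to 406 (279 higher, 127 lower; without NFS1 KO replicate 2), with 21, 35, 14 and 25 without WT replicates 1 and 3 and NFS1 KO replicates 1 and 3; the fewest lower genes (1) came without WT replicate 2 or NFS1 KO replicate 1. With the liver covariate DESeq2 called 36, of which 3 were lower, and 31 were among the 46; without the liver-tracking genes it called 68, all 46 among them. The log2 fold change of Nfs1 stayed between -0.56 and -0.36 and past no threshold, with adjusted p from 0.23 to 1.00.

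The 12 lists became 0 with an estimated correlation and 0 with fry, and 10 to 16 elsewhere. In 15 settings with the preset correlation 7 lists held throughout: p53 targets, mitosis, inhibitory receptors, glycolysis, hypoxia, cholesterol and fatty acid synthesis. Without a library, the mean of 2 of the 12 called lists and of 10 of the 15 others changed sign, and 9 of those 15 passed the threshold in some setting. Lists that turned while past the threshold with or without that library were S phase (-0.19 without WT replicate 3 to 0.05 without NFS1 KO replicate 2), interferon-stimulated genes (-0.18 without WT replicate 1, -0.17 without NFS1 KO replicate 2, up to 0.46 without NFS1 KO replicate 1), naive and memory genes (-0.43 without NFS1 KO replicate 2 to 0.20 without WT replicate 3) and cytosolic ribosomal proteins (-0.081 without WT replicate 1 to 0.082 without WT replicate 3). Among 131 other named genes, 2323 of 2344 values kept their sign and 9 genes passed the threshold in some setting. The median over all genes stayed within -0.017 and 0.014 under every scaling.

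No pairing by replicate number was seen: deviations of same-numbered samples correlated at -0.08, -0.39 and -0.22. Each sample correlated best with another number. WT replicate 1 went with NFS1 KO replicate 3 (0.32) and WT replicate 2 with NFS1 KO replicate 1 (0.42). WT replicate 3 went with NFS1 KO replicate 2 (0.49). No fit blocked on these pairs, so a pairing under other numbers was not tested. With 3 samples per genotype, deviations from the genotype's mean cannot all correlate in the same direction, so some pairs match whatever the design. WT replicate 2 and NFS1 KO replicate 1 also held the least liver transcript of their genotypes (6329 and 2158 CPM). A shared origin of same-numbered samples is therefore not excluded. With the replicate block edgeR called 0 genes, DESeq2 41 (37 higher, 4 lower) and camera 11 lists, losing S phase.

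Over 10 splits of the 6 libraries into 3 and 3, a share under 0.05 cannot be reached. edgeR called 0 genes in the real split and at most 0 in the others, and 10 of 10 gave as many. DESeq2 called 46 in the real split and up to 623 in another (WT replicate 1 with NFS1 KO replicates 1 and 3), which points to a structure of the samples other than genotype; 3 splits gave as many. Camera called 12 lists, and up to 17 elsewhere; 6 splits gave as many. It called the p53 list in 6 of the 9 other splits too (lowest adjusted p = 3.7e-06), with an absolute mean of at most 0.52 against 0.83 in the real split. Depth limits genes of a few counts, where 1 count is 0.048 to 0.071 CPM.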

Other observations

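The tests of unedited cells, of a wrong label, of the knockout as a source of stromal transcripts and of liver RNA were chosen after the results they measure were seen. DESeq2's calls outside the 27 lists, of which 6 are named here after their values were seen, were not tested for a shared function. Tnfsf4, which encodes the ligand OX40L, was 7.26-fold higher in NFS1 KO (DESeq2 adjusted p = 2.2e-08, higher in 3 of 3 libraries than in all WT). Cd80, which encodes a ligand of CD28, was 4.63-fold higher (DESeq2 adjusted p = 0.0010) and Tnfsf8, which encodes the CD30 ligand, 2.93-fold higher (DESeq2 adjusted p = 0.0024). The kinase genes Ak1 and Ckmt1 were 11.3-fold and 5.82-fold higher, from WT means of 1.19 and 0.752 CPM, and the integrin gene Itga7 was 5.66-fold lower. In each of the higher genes NFS1 KO replicate 1 was the highest knockout library and replicate 2 the lowest. Cd80 had 102 CPM in replicate 1 and 26.9 CPM in replicate 2, and Ak1 had 22.7 and 5.3 CPM. For each of the 6 named genes edgeR's adjusted p was at least 0.799. Of the 27 lists, p53 targets held 6 of the 46 calls (Fisher's exact test, adjusted p = 1.2e-08) and glycolysis 4 (adjusted p = 9.4e-06). That test takes genes as independent, while camera's estimated correlation was 0.17 and 0.47 for these lists. Camera's adjusted p with an estimated correlation was 0.23 and 0.41, and the 46 calls ranged from 13 to 406 when a library was left out. Over all 14796 genes 9.97% separated the genotypes without overlap, where chance gives 10%.

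The first pattern is the graded response among the NFS1 KO libraries: mean log2 changes of the p53 targets were 1.15, 0.50 and 0.83, and replicate 2 was closest to WT replicate 3 over all genes (chi-square per degree of freedom 6.44). Sequencing depth is argued against by thinning every library to 14094369 counts. It left a gap of 0.67 (SE 0.18 over genes) between replicates 1 and 2, no smaller than the 0.65 before thinning. That gap lay less than 1 SE above the bound of 0.5 set beforehand. Whether replicate 2 is a WT library under a wrong label is not settled. Its p53 mean lay 0.46 above the highest WT library, where the WT libraries spanned 0.12, which goes against a wrong label. The p53 list was picked out in these same data, although its mean without NFS1 KO replicate 2 was also high, at 0.99. The closeness of replicate 2 to WT replicate 3 over all genes goes the other way. Different shares of unedited cells stay open: the p53 change in replicate 2 was 22.7% of that in replicate 1 on the linear scale, which predicts a mean change of -7.24% for 69 glycolysis, hypoxia and cholesterol genes, and the observed -34.4% differed by -27.1 percentage points (95% bootstrap interval over genes -33.1 to -20.5), but that interval leaves out the spread between libraries, and the WT libraries' own means for these genes ranged over 44.5 points. That form of the test replaced an earlier one, the difference between the 2 gene groups' ratios of replicate 2 to replicate 1 (0.85, interval 0.60 to 1.24), whose interval against WT replicate 3 alone, from -3.85 to 9.21, did include 0. Nfs1 transcript was 33.3%, 12.6% and 31.3% below the WT mean in NFS1 KO replicates 1 to 3. Replicate 2 was thus the least reduced and also had the smallest p53 change. Replicates 1 and 3 were close in Nfs1 but not in p53 mean, and the transcript does not measure the loss of the protein. A p53 response that varies between knockout samples for biological reasons may remain as a hypothesis too. When and how far the NFS1 protein was lost in each sample was not measured.

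The second pattern is the presence of stromal and myeloid transcripts, lower in NFS1 KO replicate 1 than in the other 5 libraries. Cells carried over from spleen and lymph nodes as the whole source are argued against by the liver list, at least 6329 CPM in those 5 libraries, and the NFS1 knockout as the cause by the other 2 knockout libraries: 1 of them, replicate 3, lay within the WT range for the sum of 8 stromal markers, much of which is Pecam1, and both did for the 5 matrix genes (126 and 108 CPM, WT 82.8 to 133 CPM). RNA or reads of another tissue's library are a candidate source, since the liver list reached 10460 CPM and 864 genes, by limits chosen after the data were seen, kept a near-constant ratio to it and took 1.20% (NFS1 KO replicate 1) to 5.61% (WT replicate 1) of the counts; reordering the liver values gave at most 7 such genes with the lowest value in another library, and up to 866 where near-equal values changed places. The level in NFS1 KO replicate 1, relative to the mean of the other 5, was 0.24 for Alb, 0.25 for Col3a1, 0.28 for Mpeg1 and 0.25 for the Y-linked gene Ddx3y (11.2 to 19.1 CPM in the other 5, beside 609 to 1271 CPM of the X-inactivation gene Xist), but 0.47 for Ighm. Whether the liver material entered as tissue, as RNA or as reads of another library stays open.

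The third pattern is the lower glycolysis, hypoxia, cholesterol and fatty acid lists, in view of the liver's own lipid genes. Less liver RNA in the NFS1 KO libraries might lower such lists. Without NFS1 KO replicate 1 the liver list averaged 9203 CPM in NFS1 KO against 8600 CPM in WT, and the 4 lists still had means of -0.50, -0.62, -0.61 and -0.32 (camera adjusted p at most 6.3e-06), which argues against liver RNA as their whole cause. Only Rora and Scd1 among the tested members of these lists tracked the liver transcripts. An effect of the knockout stays open as a hypothesis, since camera's calls did not hold with an estimated correlation.

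Other organ lists, given as values only, summed to 90.0 to 172 CPM for brain, mostly from Mbp, to 52.0 to 197 CPM for intestine, mostly from Apoa4, which liver also expresses, and to 13.7 to 60.0 CPM for fat. Lung, pancreas, skeletal muscle, testis, heart, skin and kidney lists reached at most 8.75, 9.13, 14.3, 15.8, 2.43, 2.09 and 0.356 CPM.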
